A study of Mus musculus with 4 samples.

How the data were processed

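Droplet 3' single-cell RNA libraries were made from pooled omental tumors of 3 mouse cancer lines (KPCA.A, KPCA.B, KPCA.C) and from KPCA ascites, with 1 library per group. The deposited count matrices hold raw UMI counts per gene and cell barcode, written by the authors with Cell Ranger 4.0.0 for the tumors and 3.0.2 for ascites per the file headers, while the labels give Cell Ranger 3.1.0 and build mm10. The deposited gene and barcode tables hold other values, namely gene identifiers, symbols and cell barcodes in the order of the matrix. The labels give the same chemistry for all libraries. Barcodes that begin with AAACCC numbered 9 in KPCA.A, 3 in KPCA.B, 4 in KPCA.C and 0 in ascites. Those that begin with AAACCT numbered 0 in each tumor and 5 in ascites. Against the labels, tumors and ascites may thus have had different barcode sets and chemistry. No further normalization is stated per the labels. The annotations list 32285 genes for the tumors and 31053 for ascites, of which 30406 are shared by identifier. Shared genes hold 99.6%, 99.6%, 99.5% and 99.9% of the UMIs of KPCA.A, KPCA.B, KPCA.C and ascites.

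Barcodes with at least 300 genes, at least 500 UMIs and at most 15% mitochondrial UMIs were kept. Scrublet in scanpy 1.11.5, with an expected rate of 0.8% per 1000 barcodes, marked 38 of 11253 cells (0.338%), so its automatic threshold has not worked and doublets remain in all classes. Counts were scaled to 10000 per cell and logged, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2, igraph 0.11.9, seed 1) were used on all libraries together without integration. Computation used python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19 and matplotlib 3.10.9. Clusters took the name of the class with most markers, at least 3, among their 50 leading genes, and mixed clusters were clustered again. A cluster stayed unnamed where another class had more markers among its 10 leading genes, which left out 2 clusters led by plasma cell markers (97 KPCA.B cells). Names end in "-like" since they rest on markers alone. This gave 13 named classes from 51 clusters and sub-clusters, with 4 clusters left unnamed. Sub-clustering, and the limits that set tumor epithelial-like clusters (Krt8 and Krt18 at 500 CPM, Cdkn2a at 200 CPM), were set after the data were seen. The lowest Cdkn2a level of a tumor cluster was 351 CPM and the highest of any other 110.2 CPM.

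UMIs were summed per class and library and scaled to CPM over shared genes. Folds have exact conditional intervals, and shares exact Clopper-Pearson intervals. A share of 0 is given with the limit that 3 counts allow. Classes needed 50 cells in every library compared, which left tumor epithelial-like, macrophage-like and fibroblast-like cells between tumors and macrophage-like cells for ascites. No test, p-value or count of changed genes was computed, since cells are not replicates. Lists were summarised by the median log2 ratio with 5 CPM added, over members with at least 50 UMIs, and its percentile among 10000 random lists matched on expression in 20 bins. Ascites was set against each tumor and was called higher or lower only where it lay beyond all 3. Fibroblast RNA was taken off tumor epithelial-like values as the share of a marker times the fibroblast-like profile of the same library, a step chosen after the data were seen. Coordinates are those of GENCODE vM21 on GRCm38.

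The cell filter, marker sets, gene lists, comparisons and the rule for named genes were fixed before the data were examined. The rule took the genes that differ most from the nearer of the other tumors, 4 per direction and tumor in tumor epithelial-like cells, 3 in macrophage-like cells and 1 in fibroblast-like cells, and 8 per direction in ascites macrophage-like cells. It required 50 CPM, 50 UMIs and at least 50% of the highest CPM of any unrelated class in that library, so a named gene could be higher there. It left out ribosomal, mitochondrial and immunoglobulin genes. Fixed genes and the leading 3 members of lists outside the central 95% of random lists were also named. Of these list members the text gives a choice made after their values were seen. Some of the genes that the rule or the fixed set names are not reported here. Lists for T cells and neutrophils were not compared in their own classes for want of cells.

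Alternatives fixed beforehand were looser and stricter filters, doublets kept, resolutions 0.5 and 2, 30 neighbours, libraries clustered alone, median-of-ratios scaling, the mean over cells, 1 and 20 CPM added, all list members with a UMI, and cells thinned to 1000 UMIs. Added after the data were seen were removal of the highest doublet scores, cluster 2 only, removal of cluster 5, of cluster 16 or of cells with fibroblast transcripts, clusters 0 and 17 only for hypoxia, and Krt8 and Krt18 positive cells without Ptprc. On simulated counts, the intervals held the true fold for 95.4% of 12043 unchanged genes in tumor epithelial-like cells, and 2.5%, 5.5% and 4.5% of unchanged lists lay outside the central 95% in tumor epithelial-like, macrophage-like and fibroblast-like cells. These counts were independent Poisson draws from a shared profile, and the lists were random genes. The check thus covers counting error alone, not lists of co-regulated genes or differences between libraries.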

Results

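Single-cell RNA was measured in 4 droplet libraries from C57BL6J mice. They came from omental tumors of the syngeneic cancer cell lines KPCA.A, KPCA.B and KPCA.C, whose cells of origin the labels give as fallopian tube epithelium, and from KPCA ascites. Each tumor library pooled 4 tumors taken at 8 weeks of age, and the ascites was taken at 9 weeks. The labels do not say which line gave the ascites. The labels state 5000 cells per library. The matrices held 5703 barcodes for KPCA.A, 3358 for KPCA.B, 4110 for KPCA.C and 3118 for ascites, of which 2643, 2579, 3088 and 2905 were used after filtering. Total counts were 58591493, 40054369, 95130645 and 7420674 UMIs (unique molecular identifiers, each standing for 1 captured transcript). The median depth of the cells used was 7904, 7953, 14675.5 and 2084 UMIs. Each group had 1 library, so no difference reported here has a replicate check, and every interval is a 95% interval that covers counting error only.

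The first comparison asked which cell types the tumors of the 3 lines held. KPCA.A and KPCA.C tumors were mostly tumor epithelial-like and monocyte or macrophage-like cells, whereas KPCA.B tumors held many lymphocytes. Tumor epithelial-like cells made up 34.96% (exact Clopper-Pearson interval 33.1 to 36.8%) of KPCA.A cells, 15.9% (14.5 to 17.4%) of KPCA.B cells and 44.0% (42.2 to 45.8%) of KPCA.C cells. B cell-like cells were 23.1% (21.5 to 24.8%) of KPCA.B cells, against 0.605% (0.346 to 0.981%) in KPCA.A and 2.33% (1.83 to 2.93%) in KPCA.C. Neutrophil-like cells were 9.72% (8.62 to 10.9%) of KPCA.A cells, 1.67% (1.21 to 2.24%) of KPCA.B cells and 0.291% (0.133 to 0.553%) of KPCA.C cells.

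Macrophage-like cells were 32.5% (30.8 to 34.4%), 25.01% (23.3 to 26.7%) and 36.9% (35.2 to 38.7%) of the cells in the tumors of lines A, B and C in that order. T cell-like cells were 1.66% (1.21 to 2.23%), 8.72% (7.66 to 9.88%) and 5.31% (4.55 to 6.16%), and plasma cell-like cells 1.14%, 8.18% and 1.17%, or 1.21%, 11.9% and 1.42% with the cells of 2 unnamed clusters led by plasma cell markers. Within immune cells alone, B cell-like cells made up 32.2% (30.1 to 34.4%) in KPCA.B and 4.77% (3.75 to 5.97%) in KPCA.C. NK cell-like cells were 0.454%, 2.79% and 0.842%, dendritic cell-like cells 1.48%, 1.40% and 1.81%. Among stromal classes, fibroblast-like cells were 7.87% (6.87 to 8.96%) of KPCA.A, 2.60% (2.02 to 3.29%) of KPCA.B and 4.89% (4.16 to 5.71%) of KPCA.C cells. Endothelial-like cells were 3.41%, 2.25% and 0.680%, and mesothelial-like cells 1.32%, 2.33% and 0.810%. Some shares depended on the settings. With the stricter cell filter the mesothelial-like shares were 1.71%, 0.225% and 1.12%, so KPCA.B went from the highest to the lowest, and its plasma cell-like, NK cell-like and fibroblast-like shares were 13.8%, 6.52% and 4.58%. At Leiden resolution 2 its T cell-like share was 5.54%. With each library clustered alone the B cell-like share of KPCA.A was 1.82% and the fibroblast-like shares of KPCA.A and KPCA.B were 5.30% and 4.89%.

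Of the KPCA.A barcodes, 53.1% lay over the mitochondrial limit, against 22.5% for KPCA.B and 24.3% for KPCA.C, so the filter weighed on KPCA.A most. Free RNA was visible. The antibody light chain gene Igkc reached 701 CPM (the UMIs of the gene scaled to a common total per class and library) in KPCA.B tumor epithelial-like cells and 54.5 CPM in those of KPCA.A, and Krt8 was 50.3 CPM in macrophage-like cells of KPCA.A.

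**Figure D1:**
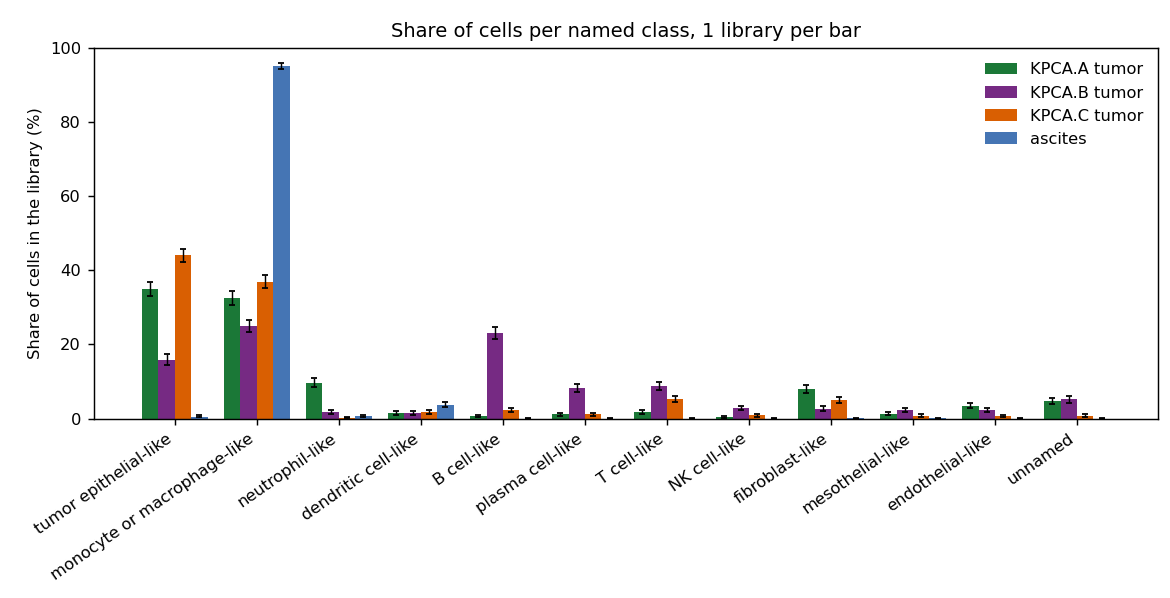
Share of cells in each named class, in percent of the cells used, with 1 bar per library and exact 95% Clopper-Pearson intervals for counting error as error bars. B cell-like cells reach 23.1% in KPCA.B and macrophage-like cells 95.04% in ascites.

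The second comparison set the tumor epithelial-like cells of the 3 lines against each other (924, 410 and 1359 cells). Several of the genes that differed most were secretory genes carried by a minority of the cells. In KPCA.A, Gkn1, a gastric mucosal protein, was at 560 CPM, 121-fold (92.2 to 161) above KPCA.B, and Gkn2 was 121-fold (88.5 to 170), the trefoil factor Tff1 77.6-fold (61.3 to 99.5) and pepsinogen C (Pgc) 361-fold (141 to 1325) higher. In KPCA.B against KPCA.A, Spink4 was 22.2-fold (20.1 to 24.5) higher, the mucus protein gene Fcgbp 80.9-fold (56.2 to 121) and the trefoil factor Tff3 1172-fold (400 to 5690). Reg4 was at 105 CPM in KPCA.B and 0.0320 CPM in KPCA.A, a ratio of 3289 (589 to 130008). The ratios of Tff3 and Reg4 rest on few UMIs in KPCA.A, so their size is poorly known. Gkn1 in KPCA.A was at 2192 CPM in cluster 16 (161 cells) and 987 CPM in cluster 5, whose cells have few UMIs, but at 5.43 CPM in cluster 2 (567 cells). Tff3 in KPCA.B was at 408 CPM in cluster 16 (73 cells) and absent from clusters 2 and 5. Without cluster 16 the log2 ratios fell from 6.91 to 1.66 for Gkn1, from 6.92 to 0.90 for Gkn2, from 6.28 to 1.17 for Tff1, from 4.47 to 2.75 for Spink4, from 6.34 to 3.09 for Fcgbp and from 11.7 to 1.504 for Reg4, and Pgc stayed at 7.86. Some of these genes were found in other KPCA.A classes as well, Pgc at 71.9 CPM in neutrophil-like and 20.1 CPM in macrophage-like cells against 126 CPM in tumor epithelial-like cells, and Tff1 at 109.5 CPM in T cell-like and 14.4 CPM in macrophage-like cells against 475 CPM, so free RNA may add to their values. The protocadherin gene Pcdh7 was 24.9-fold (21.6 to 28.9), the growth factor gene Bmp2 22.9-fold (18.8 to 28.3) and the transcription cofactor Lmo1 146-fold (85.5 to 275) higher in KPCA.C than in KPCA.A, and the axon guidance gene Sema3a was 8.14-fold (7.23 to 9.20) higher than in KPCA.B.

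Among the genes lowest in 1 line, Lmo7 was 3.03-fold (2.70 to 3.40), the cystine transporter gene Slc7a11 2.53-fold (2.36 to 2.72), metallothionein Mt2 2.31-fold (2.20 to 2.43) and Ncam1 2.15-fold (1.98 to 2.32) lower in KPCA.A than in the nearest line. In KPCA.B, the BMP antagonist Grem1 was 18.7-fold (13.7 to 26.1), the EGF receptor ligand Areg 7.43-fold (5.99 to 9.31) and Hs6st2 5.56-fold (4.77 to 6.52) lower. KPCA.C had less Wfdc18 (240-fold, 177 to 335), lipocalin Lcn2 (58.5-fold, 51.8 to 66.3), Prap1 (892-fold, 408 to 2436) and Epcam (32.4-fold, 29.6 to 35.6), the last an epithelial adhesion gene (ENSMUSG00000045394, GRCm38 chromosome 17, 87635979 to 87651129). Cluster 16, which held only 4 KPCA.C cells, carried much of these falls, though less of those of Lcn2 and Wfdc18 against KPCA.B. Within cluster 2, Lcn2 was at 10.2, 274 and 6.32 CPM in the order A, B, C. The log2 ratios of KPCA.C to KPCA.A and KPCA.B there were -0.68 and -5.44 for Lcn2, -1.30 and -5.23 for Wfdc18 and -4.797 and -3.38 for Prap1, against -5.87 and -7.57, -7.91 and -9.81, and -10.8 and -9.80 over the class. The higher values of Pcdh7, Bmp2 and Sema3a in KPCA.C were smaller within cluster 2 too, at 2.82, 1.83 and 0.67 log2, whereas that of Lmo1 stayed within its interval.

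Of 28 measured epithelial junction and keratin genes, 27 were lower in KPCA.C than in KPCA.A and 26 lower than in KPCA.B, with medians of -1.39 and -1.46 log2, below all 10000 random lists. Epcam was at 255, 378 and 7.85 CPM in the order A, B, C, Krt8 at 2405, 1031 and 1311 CPM, and Krt18 at 1908, 1067 and 868 CPM. The mesenchymal list was higher in KPCA.C, with 23 of 32 members above KPCA.A (median 0.40) and 25 above KPCA.B (median 0.94). Its collagen gene Col3a1 was at 383, 92.0 and 750 CPM and its transcription factor Twist2 at 39.8 CPM in KPCA.C against 3.50 in KPCA.B. Fibroblast genes rose with it in these cells, Dcn at 5.09, 56.4 and 213 CPM and Pdgfra at 1.99, 2.36 and 17.3 CPM. With fibroblast RNA taken off at the share read from Dcn, the medians were -0.11 and 0.32 and Col3a1 was at 27.9 CPM in KPCA.C, and at the share read from Lum they were 0.097 and 0.83, so RNA of fibroblasts may account for the rise against KPCA.A and for part of that against KPCA.B. Twist2 stayed at 39.0 against 3.35 CPM at the share from Dcn. Fallopian tube and Mullerian genes were higher in KPCA.B than in KPCA.C (18 of 21, median 1.13) and KPCA.A (15 of 21, median 0.45); Pax8 was at 44.0, 62.0 and 18.997 CPM. KPCA.A and KPCA.B cells of this class lay mostly in clusters 2, 5 and 16, those of KPCA.C in clusters 7, 5, 14 and 2. Cluster 16 held 96.1% of the class's Epcam UMIs in KPCA.A and 94.1% in KPCA.B. Epcam in macrophage-like cells, which should lack it, was at 9.10, 1.40 and 4.45 CPM. Within cluster 2 Epcam was at 11.3, 31.6 and 25.2 CPM, so its direction between KPCA.C and KPCA.A turned there, from -5.02 to 1.16 log2. The junction list kept its direction within cluster 2, at -0.44 log2 against KPCA.A. Without cluster 16 it was at -0.72.

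Hypoxia genes were lower in KPCA.B: 24 of 25 lay below KPCA.A (median -0.95) and 23 below KPCA.C (median -1.24). Vegfa, the main angiogenic growth factor (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369), was at 349, 86.5 and 292 CPM, and the mitophagy gene Bnip3 at 239 CPM in KPCA.A against 46.1 in KPCA.B. Glycolysis genes followed, with medians of -0.50 and -0.75 and 14 of 17 members lower in each case; Pgk1 was at 1029, 418 and 1715 CPM. The angiogenesis list (medians -0.25 and -0.55), ERK pathway output (-0.40 and -0.41), with Myc at 54.1, 15.9 and 52.3 CPM, and myeloid-recruiting factors (-0.32 and -0.62) were lower in KPCA.B than in KPCA.A and KPCA.C. The monocyte chemokine gene Ccl2 was at 156, 34.7 and 370 CPM, and Cxcl1, which attracts neutrophils, at 0.352, 9.10 and 0.785 CPM. The NF-kB list had medians of 0.30 and 0.33 for KPCA.B against KPCA.A and KPCA.C, mitosis 0.31 and 0.23, and oxidative phosphorylation 0.27 and -0.06; the last 2 lists lay within the central 95% of random lists against KPCA.C. Matrix remodeling was lower in KPCA.B than in KPCA.C (-0.63), with osteopontin (Spp1) at 2290 against 15054 CPM, and had a median of 0.00 against KPCA.A. The list named AKT and MTOR output was lower than in KPCA.C (-0.48), with 17 of 19 members down. It holds Atf4, Ddit3, Trib3, Chac1 and genes of amino acid synthesis and transport such as Asns, Psat1, Phgdh and Slc7a5. In every class its value stands for these genes and is no measure of AKT or MTOR activity.

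Type I interferon genes had medians of -0.68 and -0.61 in KPCA.B against KPCA.A and KPCA.C, with Isg15 at 61.2, 20.7 and 94.2 CPM. This direction did not hold with each cell weighted alike, where the medians were 0.35 and 0.05. MHC class II genes were lower in KPCA.C than in KPCA.A (-1.41) and KPCA.B (-1.66), at a low level. Cd74 was at 183, 259 and 53.9 CPM here, against 10616, 9822 and 6220 CPM in macrophage-like cells and 68.5, 277 and 125 CPM in T cell-like cells. For KPCA.B against KPCA.A and KPCA.C, MHC class I (-0.01 and 0.08), interferon gamma response (0.07 and 0.26), S phase (0.12 and 0.19), p53 targets (-0.08 and -0.10), cholesterol synthesis (0.03 and 0.00) and dissociation stress (-0.12 and -0.26) had small medians. Lymphocyte-recruiting chemokines had 0.11 and 0.41, and checkpoint ligands and suppressors -0.09 and -0.28. Of these lists, dissociation stress, lymphocyte-recruiting chemokines and checkpoint genes lay outside the central 95% of random lists against KPCA.C, at percentiles 1.10, 98.3 and 0.320, and the other values lay inside. Of the genes fixed for their role in tumors, Ccne1 was at 9.96, 20.6 and 7.08 CPM, Trp53 at 32.4, 18.99 and 77.0, Akt2 at 44.9, 54.8 and 48.7, B2m at 1055, 849 and 1328, Cd274 at 7.43, 5.42 and 4.80, and Wt1 at 0.673, 0.350 and 0.361 CPM.

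**Figure D2:**
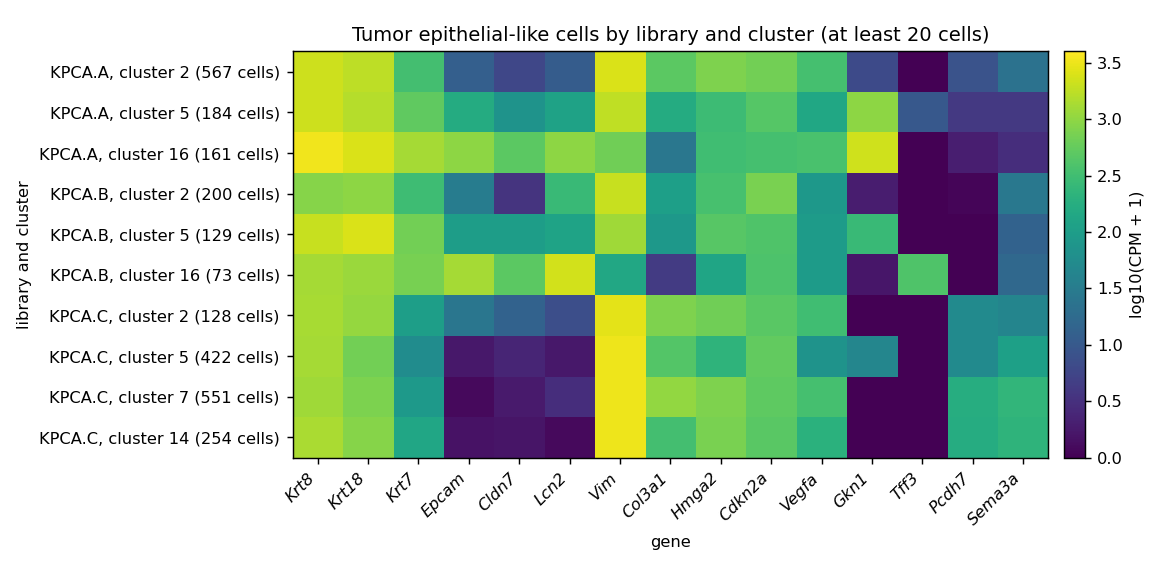
Expression of 15 genes (log10 of CPM + 1, color) in tumor epithelial-like cells of each library and cluster with at least 20 cells. Epcam is highest and Vim lowest in cluster 16 of KPCA.A and KPCA.B. Pcdh7 is highest in the KPCA.C clusters, whereas Vim is high there and also in cluster 2 of KPCA.A and KPCA.B.

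The third comparison took the monocyte or macrophage-like cells of the tumors (860, 645 and 1141 cells). Over the whole class, KPCA.B macrophage-like cells had lower levels of hypoxia and inflammatory genes. They had higher levels of mitosis genes and of the large peritoneal macrophage program. Retnla, a gene of alternatively activated macrophages, was at 10043 CPM in KPCA.B, 20.5-fold (20.03 to 21.0) above KPCA.C. The resident macrophage marker Lyve1 was 8.55-fold (7.52 to 9.74) higher than in KPCA.C, and the ribonuclease gene Ear2 4.97-fold (4.48 to 5.53) higher than in KPCA.A. Vegfa was 14.7-fold (12.4 to 17.6), Rgs1 9.73-fold (9.01 to 10.5) and Ifitm1 11.3-fold (9.38 to 13.8) lower in KPCA.B than in the nearest line.

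In KPCA.A, genes of large peritoneal macrophages were lowest. The lipoxygenase gene Alox15 (ENSMUSG00000018924, chromosome 11, 70344152 to 70352031) was at 4.81, 376 and 236 CPM in the order A, B, C. Cd5l was 12.2-fold (9.15 to 16.5) below KPCA.C. Ucp1, which is not in the large peritoneal list, was low in KPCA.A too, at 0.343 CPM, a ratio of 152 (41.9 to 1256) that rests on few UMIs there. Of 33 genes of the large peritoneal program, 31 were lower in KPCA.A than in KPCA.B and 31 lower than in KPCA.C. The medians were -1.87 and -0.92. Of the 33 genes, 27 were higher in KPCA.B than in KPCA.C (median 0.73). The program's transcription factor Gata6 was at 5.32, 37.8 and 19.1 CPM and Timd4 at 0.687, 15.5 and 3.39 CPM. In cells thinned to equal depth, Gata6 was found in 0.857% (0.345 to 1.76%), 3.2% (1.97 to 4.9%) and 1.01% (0.507 to 1.81%). The intervals of KPCA.A and KPCA.C overlapped there, so the Gata6 difference between these tumors was not seen at equal depth. Gata6 was higher in fibroblast-like cells, at 284, 234 and 274 CPM, so free RNA or doublets may add to its values here. The interferon-induced chemokine gene Cxcl10 was 3.02-fold (2.72 to 3.37), the elastase Mmp12 2.17-fold (2.10 to 2.25) and Tgfbr1 2.22-fold (1.98 to 2.499) higher in KPCA.A than in the nearest line. In KPCA.C, the carbonic anhydrase gene Car4 was 5.82-fold (4.66 to 7.36) and thrombospondin Thbs1 2.88-fold (2.77 to 2.99) higher than in KPCA.A. The chemokine gene Ccl17 was 2.72-fold (2.47 to 3.01), Cx3cr1 2.64-fold (2.42 to 2.88) and the lipase Lpl 2.30-fold (2.08 to 2.55) lower there than in the nearest line.

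Of 24 hypoxia genes, 23 were lower in KPCA.B than in KPCA.A (median -1.11) and 24 lower than in KPCA.C (median -1.37); Hilpda was at 183, 25.05 and 270 CPM. The inflammatory macrophage list had medians of -1.62 and -1.75, with Il1b at 813, 97.8 and 582 CPM and Ptgs2, the prostaglandin synthase gene, at 129, 6.80 and 93.5 CPM. Myeloid-recruiting factors had medians of -1.61 and -1.83, with Cxcl2 at 543, 66.8 and 576 CPM. The dissociation stress list was lower in KPCA.B as well (-0.81 and -0.79), with Fos at 640, 109 and 663 CPM. Whether dissociation stress brings part of the fall of the inflammatory list was not tested. ERK output (-0.79 and -0.996), angiogenesis (-0.73 and, inside the random range, -0.15), matrix remodeling (-0.72 and -0.55) and glycolysis (-0.29 and -0.56) had negative medians too. Proliferation genes were higher in KPCA.B. Of 33 mitosis genes, 32 lay above KPCA.A (median 0.86) and 33 above KPCA.C (median 1.37), and the S phase list had medians of 0.30 and 0.84; Mki67 was at 56.8, 180 and 36.0 CPM. Oxidative phosphorylation had medians of 0.44 and 0.27.

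MHC class II genes were lower in KPCA.C than in KPCA.A (9 of 10, median -0.74) and KPCA.B (7 of 10, median -0.65), with H2-Ab1 at 3250, 3112 and 1827 CPM. Type I interferon genes were higher in KPCA.C than in KPCA.A (27 of 31, median 0.33), and interferon gamma response genes lower (22 of 26, median -0.33). Against KPCA.A and KPCA.C, KPCA.B had medians of -0.48 and 0.14 for NF-kB, -0.82 and -0.16 for lymphocyte-recruiting chemokines, -0.11 and 0.00 for the tissue-repair list, 0.05 and -0.20 for the monocyte list, -0.13 and -0.12 for MHC class I, -0.20 and -0.26 for checkpoint genes, -0.15 and -0.19 for the mesenchymal list, 0.13 and -0.17 for AKT and MTOR output, -0.05 and -0.09 for p53 targets and -0.04 and 0.10 for cholesterol synthesis. Outside the central 95% of random lists were NF-kB, lymphocyte-recruiting chemokines and checkpoint genes against KPCA.A, and the monocyte list, checkpoint genes, the mesenchymal list and AKT and MTOR output against KPCA.C. Most lists lay outside in this class, 23 of 34 between KPCA.A and KPCA.B and 24 of 34 between KPCA.B and KPCA.C. The direction of the monocyte list against KPCA.C turned with each cell weighted alike (0.035) and with cells thinned to 1000 UMIs. Arg1 was at 4739, 4886 and 8182 CPM, Mrc1 at 756, 694 and 1209, Ccr2 at 785, 797 and 771, C1qa at 2934, 3457 and 2427, Trem2 at 195, 165 and 186, Cxcl9 at 295, 278 and 162 and Cd274 at 98.2, 27.6 and 101 CPM. KPCA.A and KPCA.C cells of this class lay mostly in clusters 0 and 9, KPCA.B cells in clusters 11 and 15. Within cluster 0 (510, 90 and 746 cells) the hypoxia list kept its direction, at -0.65 and -0.95, a smaller fall than over the class. The inflammatory, mitosis and large peritoneal lists were not compared within a cluster. Cluster 11 held 2.67%, 49.3% and 1.93% of the class, so a different mix of clusters may bring part of those differences. The epithelial junction list had medians of -0.81 and -0.69 here, with Krt8 at 50.3, 5.94 and 48.0 CPM.

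**Figure D3:**
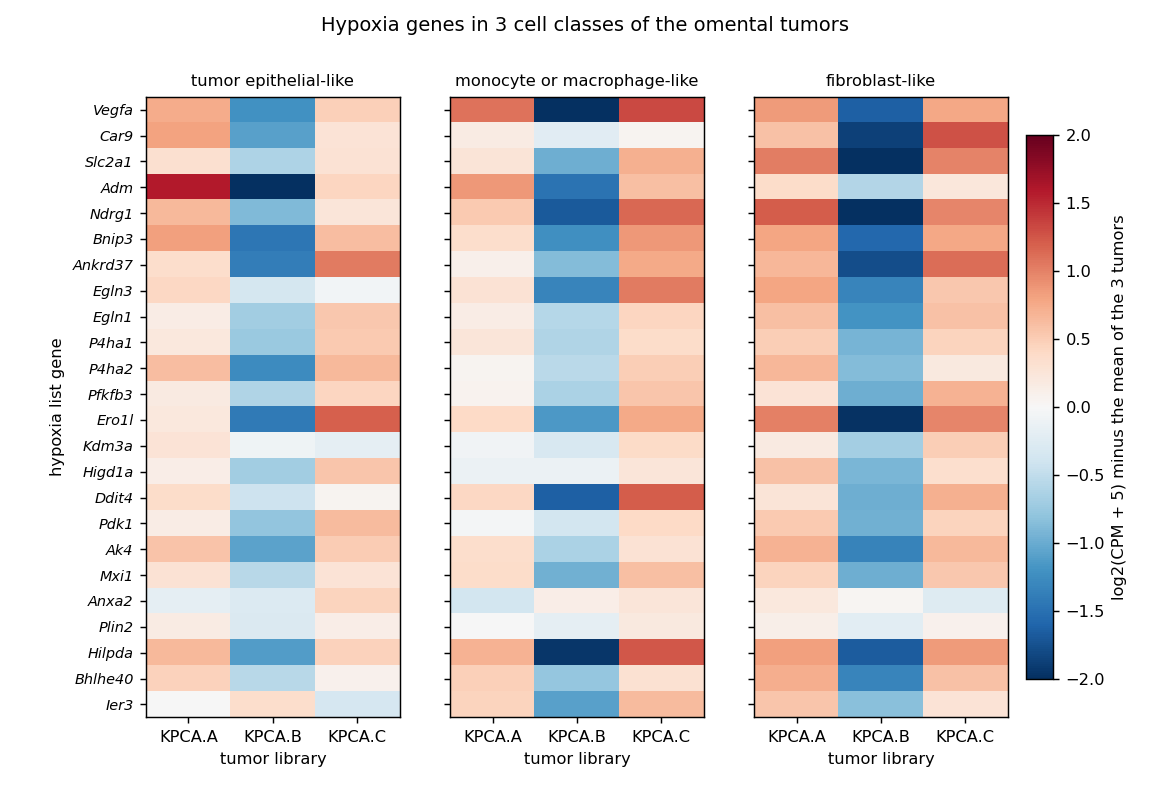
Hypoxia list genes in 3 cell classes, as log2 of CPM + 5 minus the mean of the 3 tumors (color), with 1 column per tumor library. Most genes of the KPCA.B column lie below the mean in each class.

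The fourth comparison covered the other classes with at least 50 cells in each tumor, which were the fibroblast-like cells alone (208, 67 and 151 cells). Hypoxia genes were lower in KPCA.B here as well, 25 of 25 against KPCA.A (median -1.53) and 24 of 25 against KPCA.C (median -1.69), and glycolysis had medians of -1.24 and -1.14. Ndrg1 was at 394, 33.0 and 336 CPM and the glucose transporter gene Slc2a1 at 158, 14.6 and 154 CPM. The makeup of the class differed, with 31.3%, 64.2% and 43.0% of its cells in cluster 17 and 23.1%, 0 and 17.2% in cluster 10.2. Within cluster 17 (65, 43 and 65 cells) the hypoxia medians were -2.38 and -1.72. Abca8a was 8.92-fold (6.88 to 11.6) higher in KPCA.B than in KPCA.C. The matrix program was lower in KPCA.B (-0.55 and -0.58), with Cthrc1 at 64.6, 4.61 and 39.3 CPM, as was angiogenesis (-0.75 and -0.70). The collagen gene Col8a1 was 3.88-fold (3.33 to 4.54) higher and the pericyte gene Rgs5 17.2-fold (10.1 to 31.7) lower in KPCA.A than in KPCA.C, and in KPCA.C Cxcl5 was 3.82-fold (3.02 to 4.87) lower than in KPCA.A. Type I interferon genes were higher in KPCA.C than in KPCA.A (29 of 30, median 0.58) and KPCA.B (27 of 30, median 0.53), with Ifit3 at 5.50, 6.15 and 45.5 CPM. Mitosis genes were lower in KPCA.C than in KPCA.A (33 of 33, median -1.04). The inflammatory program had medians of 0.23 and 0.00 for KPCA.B against KPCA.A and KPCA.C, with the B cell chemokine gene Cxcl13 at 250, 1396 and 190 CPM; its direction against KPCA.A turned with the stricter cell filter (-0.04). MHC class II genes were higher in KPCA.B (medians 1.99 and 0.82) at Cd74 levels of 175, 810 and 299 CPM. Macrophage genes moved the same way, Lyz2 at 12.1, 486 and 48.4 CPM and C1qa at 19.1, 273 and 75.5 CPM. In KPCA.B, Lyz2, C1qa and Cd74 reached 10.1%, 7.91% and 8.25% of their level in macrophage-like cells, so RNA of macrophages may account for this MHC class II difference. Mitosis genes were higher in KPCA.B than in KPCA.A (median 0.54), a direction that turned at Leiden resolution 0.5 (-0.25) and with the stricter cell filter (-0.16).

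T cell-like cells were too few in KPCA.A (44 cells) for that comparison. Gzmb, a killer cell protease gene, was at 28.4 CPM (19.6 to 39.9) in KPCA.B and 417 CPM (378 to 458) in KPCA.C, and Cd8a at 93.1 (76.4 to 112) and 154 CPM (131 to 181). Cd4 was at 230 and 179 CPM, Foxp3 at 87.9 and 104, Pdcd1 at 111 and 166, and Ifng at 41.4 and 25.7 CPM. Cluster 26 held 8.00% of the KPCA.B and 25.6% of the KPCA.C cells of the class, and cluster 8.1 35.6% and 11.0%, so the class differed in makeup. Few cells carried the Gzmb and Cd8a values. Of the UMIs in KPCA.C, 7 cells of cluster 8.7, a cluster with deep cells, held 48.2% for Gzmb and 50.6% for Cd8a, and 1 of them held 113 of the 421 Gzmb UMIs, so the intervals above are too narrow.

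The last comparison set ascites against each tumor. Macrophage-like cells made up 95.04% (94.2 to 95.8%) of ascites cells, in clusters 1, 3 and 4, which held 3 tumor cells of this class in all, so these clusters could not be told from the library itself. Dendritic cell-like cells were 3.68% (3.03 to 4.43%), tumor epithelial-like cells 0.551% (0.315 to 0.893%) and neutrophil-like cells 0.585% (0.341 to 0.935%), a share that was 10.1% with 30 neighbours, 5.58% at Leiden resolution 2 and 0 with the stricter cell filter. No T, B, plasma or NK cell-like cells were found among 2905 cells, which by counting error alone allows a share of up to 0.103% each. Whole clusters were named, so such cells within clusters of another name would be missed. With each library clustered alone, 36.0% of ascites cells were named macrophage-like, 50.8% stayed without a name and 8.47% were named eosinophil-like.

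Ascites macrophage-like cells had lower antigen presentation, interferon and mitosis genes and higher respiratory chain genes than those of every tumor. The all-gene median was -0.52, -0.53 and -0.48 log2 against KPCA.A, KPCA.B and KPCA.C, and list medians are given relative to it in this paragraph. Counts of members that were lower or higher are without it taken off, so they lean towards lower. All 10 MHC class II genes were lower than in each tumor, with medians of -2.71, -2.54 and -2.02; H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419) was at 363 CPM, 8.95-fold (8.58 to 9.34), 8.57-fold (8.22 to 8.93) and 5.03-fold (4.83 to 5.25) lower. Its regulator Ciita was at 1.49 CPM, and Cd74 at 637 CPM. In ascites dendritic cell-like cells H2-Ab1 was at 7635 CPM, against 5220, 5840 and 5314 CPM in the tumors. Interferon gamma response genes had medians of -2.11, -1.63 and -1.78, type I interferon genes -1.01, -1.05 and -1.42, MHC class I -0.86, -0.79 and -0.84, and lymphocyte-recruiting chemokines -1.57, -1.07 and -1.38. Cxcl9 was at 0.149 CPM, a ratio to KPCA.C of 1084 (194 to 42849) that rests on few UMIs in ascites. In ascites dendritic cell-like cells Cxcl9 was at 0 CPM, against 61.2, 700 and 68.1 CPM in those of the tumors. Mitosis had medians of -1.08, -1.79 and -0.59, with 33 of 33 members lower each time, glycolysis -0.82, -0.85 and -1.15, dissociation stress -1.35, -0.39 and -1.15, cholesterol synthesis -0.70, -0.53 and -0.50, AKT and MTOR output -0.47, -0.64 and -0.80 and the mesenchymal list -0.33, -0.33 and -0.46. Oxidative phosphorylation genes had medians of 1.68, 1.28 and 1.43, with Uqcrb at 1177 CPM against 181, 245 and 256. In dendritic cell-like cells this list had medians of 1.71, 1.46 and 1.63 and Uqcrb was at 876 CPM, 74.5% of its level in macrophage-like cells, so this difference was not one of macrophage-like cells alone. The large peritoneal program was higher as well (2.11, 0.56 and 1.47), with Prg4 at 1490 CPM against 6.35 in KPCA.A and Gata6 at 53.9 CPM. Against KPCA.B its median was 0.025 without the all-gene median taken off, so the rise over that tumor depended on this step. The program was higher in dendritic cell-like cells too (1.72, 2.25 and 1.62, from 6 measured members), where free RNA of macrophages may bring it. Lists lower in dendritic cell-like cells as well, against each tumor, were interferon gamma response (-0.89, -0.53 and -1.11), type I interferon (-0.24, -0.52 and -0.66), MHC class I (-0.44, -0.54 and -0.32), mitosis (-1.26, -2.13 and -0.32), dissociation stress (-1.05, -0.73 and -1.497), cholesterol synthesis (-0.78, -0.94 and -0.81), AKT and MTOR output (-0.44, -0.52 and -0.22) and glycolysis (-0.55, -0.02 and -0.799). MHC class II was not lower there, with 6 of 10 members higher against each tumor and medians of 0.33, 0.12 and 0.13 without the all-gene median taken off.

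Of single genes, Wfdc17 reached 37950 CPM, 37.7-fold (36.9 to 38.5) above KPCA.B, Wfdc21 was 53.8-fold (50.6 to 57.2), the protease inhibitor Slpi 20.8-fold (19.7 to 21.98), Lcn2 47.4-fold (34.8 to 66.2) and Rflnb 24.2-fold (19.8 to 30.0) above the nearest tumor. Ear6 was at 206 CPM, a ratio to KPCA.B of 1908 (342 to 75397) that rests on few UMIs in KPCA.B. S100a8, a neutrophil gene, was at 1940 CPM, 245-fold (204 to 298) above KPCA.C, and Ptp4a1 was 128-fold (98.7 to 168) higher. These genes were higher in ascites dendritic cell-like cells too, from 7.99% of the macrophage-like level for Rflnb to 27.7% for S100a8. Macrophage genes reached from 4.17% (Prg4) to 18.6% (Lyz2) there, with Arg1 at 10.1% and C1qa at 9.67%, so free RNA of macrophages may account for part of it. Above that range were S100a8, Lcn2 (20.7%), Ptp4a1 (19.4%) and Wfdc17 (18.7%). Wfdc17, Wfdc21, Slpi, Lcn2 and S100a8 belong to the neutrophil marker set. The neutrophil-like share of ascites was higher with 30 neighbours and at Leiden resolution 2. Cells that those settings name neutrophil-like may thus carry part of these values, which was not tested. Atp6v0c (414-fold lower, 251 to 739), Rnasek (109-fold lower, 60.8 to 219) and Lars2 (40.9-fold lower, 31.0 to 55.0) differed alike in both classes. The lectin gene Mgl2 was 129-fold (79.2 to 225), the receptor gene Lilrb4a 48.5-fold (33.7 to 72.7) and Timm23 89.1-fold (42.9 to 223) lower. These were lower in dendritic cell-like cells too, Timm23 at 6.90 CPM against 64.8, 76.0 and 120.5, Lilrb4a at 10.3 CPM against 216, 81.9 and 228, and Mgl2 at 204 CPM against 908, 415 and 1310. Apoc2 was at 0.149 CPM, a ratio of 595 (107 to 23545) that rests on few UMIs in ascites. C1qa was 6.18-fold (5.94 to 6.44), Trem2 4.61-fold (4.02 to 5.30) and Ccr2 6.49-fold (6.04 to 6.99) below the nearest tumor, and Arg1 was at 4703 CPM. The ascites library also differed in annotation, software, depth and age. Its first barcodes begin with other bases than those of the tumors. The chemistry may thus have differed too, although the labels give the same for all libraries. Where dendritic cell-like cells changed alike, the design cannot separate these from the site.

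**Figure D4:**
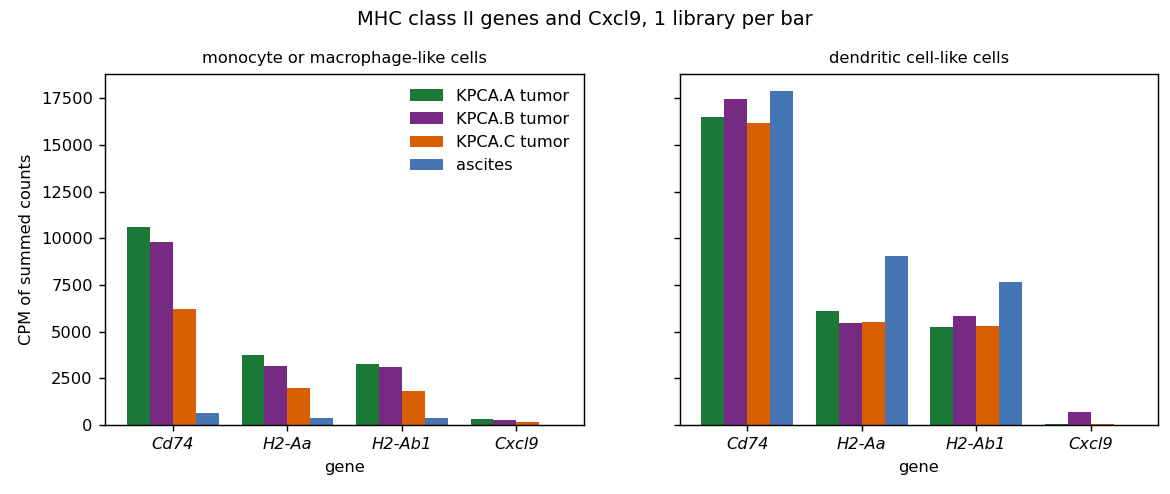
Summed counts scaled to a common total (CPM) of 4 genes in macrophage-like and dendritic cell-like cells, with 1 bar per library and no error bars. Cd74, H2-Aa and H2-Ab1 are lowest in ascites among macrophage-like cells but not among dendritic cell-like cells.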

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

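The tests of dissociation stress, of free tumor RNA, of the fibroblast RNA share and its removal, of the low-UMI cluster alone and of the dendritic cell-like cells were chosen only after the results were seen, as were the alternatives restricted to clusters 0, 2 and 17, without cluster 5 and without cells with fibroblast transcripts.

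Signals outside the comparisons were 97 cells of cluster 22, led by duct-type genes, 78 cells of cluster 25, led by pancreatic acinar genes, and 95 cells of a cluster without a name, led by immunoglobulin genes, in the 3 tumors. Genes that the ascites annotation lacks held 0.417% of the UMIs of KPCA.A, 0.401% of those of KPCA.B and 0.510% of those of KPCA.C.

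Hypoxia genes were lower in KPCA.B in tumor epithelial-like, macrophage-like and fibroblast-like cells. Weaker dissociation stress was excluded as the whole cause in tumor epithelial-like cells. That list changed there by 0.128 and 0.210 of the hypoxia list's change against KPCA.A and KPCA.C. In macrophage-like cells, however, the ratios were 0.733 and 0.574. Free tumor RNA would need 84.9% of the RNA of KPCA.A macrophage-like cells, against 2.09% read from Krt8. With cells thinned to 1000 UMIs the median in tumor epithelial-like cells was -1.08. A different mix of clusters was not the whole cause, since the medians were -0.65 and -0.95 within cluster 0 of macrophage-like cells and -2.38 and -1.72 within cluster 17 of fibroblast-like cells. Handling of the single libraries and biology of the line cannot be told apart, since KPCA.B has 1 library.

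Epithelial junction genes were lower and mesenchymal genes higher in KPCA.C tumor epithelial-like cells. Fibroblast RNA reached at most 8.25%, against the 96.9% that the fall of Epcam would need, so it does not account for that fall. For the mesenchymal genes fibroblast RNA was not excluded. Without cells holding fibroblast transcripts the median against KPCA.B was 1.19, but 356 of the 608 KPCA.C cells kept lay in the low-UMI cluster, where a missing transcript says little. With fibroblast RNA taken off at the share read from Dcn, Pdgfra and Lum the median was 0.32, 0.44 and 0.83, against 0.94, and these shares assume that the tumor cells make none of the 3 transcripts. The low-UMI cluster alone did not account for the fall, which was -1.38 without it. Within cluster 2 the junction median of KPCA.C against KPCA.A was -0.44, and over the whole class it was -1.39. A different mix of clusters may thus account for most of the fall against KPCA.A, while more of the fall against KPCA.B stayed within cluster 2. That test is partly circular, since the clusters were made from genes that include this list, and whether the clusters are cell states of the line or features of 1 library stays open.

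MHC class II and interferon gamma response genes were lower in ascites macrophage-like cells. Chemistry, annotation or depth was excluded as the whole cause for MHC class II, whose highest median in dendritic cell-like cells was 0.33, from 39, 36 and 56 tumor cells. The class differed in makeup, since all ascites cells but only 48.7%, 33.3% and 32.1% of the tumor cells lay in cluster 19. Within that cluster, with 19, 12 and 18 tumor cells, the medians were 0.76, 1.17 and 1.66. Interferon gamma response genes were lower in dendritic cell-like cells too (highest median -1.18, or -0.53 relative to the all-gene median, and at most -2.52 relative to it within cluster 19), so for them a difference of the whole library, technical or biological, may be the cause. Cluster 20 had the peritoneal macrophage genes Alox15 and Cd5l among its 10 leading genes. Against its 100 tumor cells, ascites lay at -1.99 for MHC class II, without an all-gene median taken off. More macrophages like those cells would thus not account for the whole difference. Of these cells 89 came from KPCA.C, so the comparison is nearly with a single library. Only 2 came from KPCA.B, the tumor with the highest large peritoneal program, so cluster 20 does not stand for all peritoneal-type macrophages of the tumors. Other differences in macrophage makeup were not excluded. Site, age and the unstated line of the ascites were not separated.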

How the results depend on the processing

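The alternatives restricted to clusters 0, 2 or 17, without cluster 16 and without cells with fibroblast transcripts were chosen after the data were seen. No paired analysis was possible because each group has 1 library, and leaving out replicates or other splits of the samples was not possible either. Over all alternatives, 297 shares stayed within their interval and 103 moved; 3442 list medians stayed within the spread of random lists (0.5 of the width of their central 95%), 510 moved and 27 reversed; 1248 gene folds stayed, 435 moved and 19 reversed. None of the medians reversed for hypoxia in KPCA.B, for epithelial junction and mesenchymal genes of KPCA.C tumor epithelial-like cells, for the large peritoneal program of KPCA.A, or for MHC class II and interferon gamma in ascites. The removal of fibroblast RNA is not counted among these alternatives. At the share read from Dcn it turned the mesenchymal median of KPCA.C against KPCA.A from 0.40 to -0.11. Depth was lowest in ascites (2084 UMIs per cell) and limits its values for genes of low expression. The cause was not tested for any change below, except that a larger added constant shrinks log ratios by construction. List values are median log2 ratios.

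The macrophage-like share of ascites (95.04%) was 86.0% with 30 neighbours, 89.9% at resolution 2, 93.3% with the looser filter and 36.0% with libraries clustered alone. The T cell-like share of KPCA.B (8.72%) was 5.54% at resolution 2 and 6.79% with the stricter filter. With the looser filter the KPCA.A shares were 8.55% neutrophil-like and 38.01% tumor epithelial-like. With the stricter filter macrophage-like cells were 35.4% of KPCA.A, and tumor epithelial-like cells 30.9%, 12.9% and 41.2% of the 3 tumors.

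At resolution 0.5, fibroblast-like cells of B against A gave hypoxia -1.77 and mitosis -0.25, and the fibroblast inflammatory program, median log2 fold, fibroblast-like cells, KPCA.B against KPCA.A was -0.013. At resolution 2 the monocyte program, median log2 fold, monocyte or macrophage-like cells, ascites against KPCA.A was -0.0895. With all list members, lymphocyte-recruiting chemokines in fibroblast-like cells were 0.087 (A against C), -0.12 (B against A) and -0.086 (B against C), and macrophage hypoxia (B against C) was -1.18.

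Within cluster 0, macrophage hypoxia was -0.65 and -0.95 (B against A, C), and within cluster 17 fibroblast hypoxia was -2.38 (B against A). Within cluster 2 the epithelial list was -0.44 (C against A) and -0.75 (C against B). Fallopian tube genes (-0.10) and type I interferon (0.29) reversed for A against C, as did B2m (0.16) and Epcam (-1.16; C against A 1.16). For B against C, Akt2 (-0.023) and Krt18 (-0.12) reversed. Without cluster 16 the epithelial list was -0.72 and -0.996. Without cells with fibroblast transcripts it was -1.16 (C against A), hypoxia -1.48 (B against C), the mesenchymal list 1.19 (C against B) and type I interferon 0.035 (A against C).

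With the mean over cells, hypoxia for B against A was -1.77 in fibroblast-like and -1.47 in macrophage-like cells, and -0.90 in tumor epithelial-like cells for B against C. The large peritoneal program was -1.24 (A against B) and -0.52 (A against C), and the mesenchymal list 0.20 (C against A). Reversed were oxidative phosphorylation in fibroblast-like cells (B against C, -0.027), the monocyte program (B against C 0.035, ascites against A -0.16 and B -0.21), Arg1 (A against B 0.27, ascites against B 0.13), H2-Ab1 (A against B -0.23), type I interferon in tumor epithelial-like cells (B against A 0.35, against C 0.048), Cd274 there (A against B -0.51) and Krt8 (B against C 0.061).

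With median-of-ratios scaling, ascites against A, B and C gave MHC class II -2.43, -2.24 and -1.81 and interferon gamma -1.98, -1.68 and -1.81. Arg1 (ascites against B, 0.78), Mrc1 (ascites against B, 0.11) and Ccr2 (B against C, -0.029) reversed.

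With 1 CPM added, interferon gamma in ascites was -3.15, -2.90 and -2.73, the large peritoneal program -2.62 (A against B) and -1.47 (A against C), the epithelial list -2.26 and -2.57 (C against A, B) and the mesenchymal list 0.57 (C against A). With 20 CPM added these were -1.49, -1.23 and -1.24, then -0.83 and -0.59, then -0.82 and -0.85, then 0.20, with 0.67 for C against B. Hypoxia was then -1.33 (fibroblast-like, B against C), -0.91 and -1.08 (macrophage-like, B against A, C) and -0.93 (tumor epithelial-like, B against C).

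With the stricter filter, hypoxia in fibroblast-like cells was -2.01 and -1.92 (B against A, C). Reversed there were NF-kB (B against A, 0.067), the epithelial list (A against C, -0.21), fallopian tube genes (B against A, 0.0007), the inflammatory program (B against A, -0.038) and mitosis (B against A, -0.16). In macrophage-like cells fallopian tube genes (B against C, 0.0145) and Arg1 (A against B, 0.0049) reversed, as did the monocyte program, median log2 fold, monocyte or macrophage-like cells, ascites against KPCA.A (-0.0048).

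Thinned to 1000 UMIs, hypoxia for B against A and C was -1.98 and -2.03 in fibroblast-like and -1.43 and -1.58 in macrophage-like cells. The large peritoneal program was -1.38 (A against B) and -0.68 (A against C), the epithelial list -2.02 and the mesenchymal list 1.18 (C against B). Reversed were the fibroblast inflammatory program (A against C, 0.17), the monocyte program (ascites against A -0.14 and B -0.093), Arg1 (A against B 0.27, ascites against B 0.18), H2-Ab1 (A against B -0.21), type I interferon in tumor epithelial-like cells (B against A 0.001), Akt2 (A against C 0.096) and Cd274 (A against B -1.31). The monocyte program, median log2 fold, monocyte or macrophage-like cells, KPCA.B against KPCA.C was 0.0075.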

Other observations

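Pancreatic acinar genes were found in the tumor libraries. Cluster 25 held the digestive enzyme genes Ctrb1, Clps and Prss2 at 57144, 53883 and 37621 CPM, and came from 45 KPCA.A, 22 KPCA.B and 11 KPCA.C cells. Cluster 22 held Dcdc2a at 1192 CPM, the transcription factor gene Onecut1 at 747 CPM and Pkhd1 at 620 CPM, with 79 of its 97 cells from KPCA.A. Whether its cells are pancreatic was not tested. Cela1, Pnlip and Ctrb1 were higher in KPCA.A in all 3 classes compared, by at least 1.62, 1.57 and 1.503 log2. The unnamed cluster of immunoglobulin genes, with Igkc at 204295 CPM and Ighm at 128905 CPM, had 87 of its 95 cells from KPCA.B.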
